A study of Mus musculus with 12 samples.

How the data were processed

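Native ChIP-seq was made from 100000 nuclei per library, per the labels, with 3 animals per genotype and mark. Reads were processed against mm10, and Bowtie2 2.3.4.3 and MACS2 are named in the submitters' processing notes without a version for MACS2. The tool behind the H3K9me3 comparison is not given in the sources used here. The replicates are separate animals, per the series design.

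For H3K9me3 the authors deposited 1 table of 50654 regions built from windows of 1000 bp. It holds normalised counts per library joined in 1 cell for each genotype, so which animal each of the 3 listed values belongs to is not stated, and they are called the first, the second and the third listed value here. The authors' group means are a normalised signal, per the file headers. The authors' enrichment is a ratio, per the file headers. The authors' log2 fold changes are KO over WT, per the file headers. The authors' p-values and adjusted p-values are per region, per the file headers. Only regions that the authors selected are listed, and 12 of them have an adjusted p above 0.05.

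For H3K27ac the authors deposited 1 MACS2 peak list per library. Each peak has a score, a fold enrichment and -log10 p and q values from the authors' peak caller, per the labels. These were used only to rank or filter peaks within a list.

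The authors' p-values were compared with a G-test on the summed values of each genotype with an equal split expected. Over 38105 regions with p above 1e-14 the largest difference was 0.00674 on the log10 scale. Such a test does not use the spread between animals. Each listed position holds whole multiples of 1 step, within 0.1 reads for 100% of low values at each position. The inverse of the step, taken relative to the smallest step, was 17.1%, 100% and 51.9% at the KO positions and 24.6%, 53.2% and 60.1% at the WT positions. It is a relative depth under the authors' scaling only, and the read totals have other ratios. Reads in the listed regions were 11.0, 36.4 and 13.7 M in KO and 15.9, 19.6 and 28.4 M in WT (M for mega), of which 26 regions with a WT mean above 10000 took 70.4% to 91.8%. The first listed KO value is therefore the least precise. The depth of the H3K27ac libraries is unknown. The lowest background coverage that the peak values imply was 1.17, 2.71 and 2.31 fragments per base in KO and 1.11, 2.61 and 2.55 in WT (tolerance 0.002), so the short lists of replicate 3 did not come with low background.

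Because the table turned out to hold values per library, a test with replicates was added that the fixed design had left open. limma 3.58.1 (R 4.3.3) was run on log2(value + 1) with a mean-variance trend and Benjamini-Hochberg adjustment over the listed regions. Those regions had been selected on the same libraries, so its adjusted p-values are not independent of that choice. Its fold changes are on the log2(value + pseudocount) scale. Reads of 5000 regions were simulated with the depths that the steps imply and an assumed squared coefficient of variation between animals of 0.03. There limma recovered 49 of 50 regions lowered to 0.25 times and 25 of 50 at 0.5 times. It recovered 40 of 50 raised 2 times and 50 of 50 raised 4 times, with 6 false calls. The assumed spread was not estimated from these libraries, so the simulation does not give the power or the error of limma on them. limma-voom on the recovered reads was added as an alternative.

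Gene lists were 17 sets fixed before the data were examined, of which 14 had a listed region. Members were matched by the symbols of the authors' table, some of them outdated. Each was tested with a two-sided Fisher's exact test of lower against higher regions, against all other regions. Neighbouring regions are not independent, so these p-values are too small. H3K27ac peaks on chromosomes 1 to 19, X and Y were merged where they overlapped by 1 bp. The reference of GRCm38 gave no strand, so both ends of each gene stood in for start sites, within 1 kb. This departs from the fixed design. Peak merging was checked on simulated lists, where 50 of 50 planted KO-only and 20 of 20 planted WT-only regions were found. The same simulation called 116 KO-only and 88 WT-only regions in all, the rest by chance presence of peaks, so being KO-only or WT-only is not by itself evidence of a genotype effect. KO and WT were compared with exact permutation tests, which cannot go below 0.1 with 3 against 3.

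Named genes followed a rule fixed before the data were examined. It takes Setdb1, the 12 lower and 12 higher H3K9me3 regions in genes with the smallest authors' adjusted p (ties by p, then by fold change), up to 4 members per list, the 12 leading KO-only and WT-only H3K27ac regions with a gene, and up to 12 regions with both marks. The adjusted p of many regions is listed as 0, so ties were broken by fold change. Some genes that the rule takes are not reported here. Alternatives covered thresholds, overlap rules, list length, left-out libraries and scaling. H3K27ac peaks on other sequences (39 to 61 per library) were left out. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.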

Results

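Chromatin of neural progenitors that lack Setdb1 was compared with that of wild-type (WT) progenitors. SETDB1 is a histone methyltransferase that places methyl groups on lysine 9 of histone H3, and the knockout (KO) is labelled as a Nestin-KO of it. The cells were neurosphere cultures from the ganglionic eminence of mouse embryos, the embryonic source of cortical interneurons, and each library was made from 100000 nuclei. The 12 libraries cover 2 marks, with 3 animals per genotype for each. By the numbers in the titles, no animal was used for both marks. H3K9me3 marks silenced chromatin, and H3K27ac marks active promoters and enhancers. For H3K9me3 all 3 KO animals were male, and 2 of the 3 WT animals were female, so sex and genotype are partly mixed. The first number in the H3K9me3 titles is mixed with genotype too, since 1 number is shared by 2 KO animals, another by 2 WT animals, and 1 KO and 1 WT animal share the remaining one. The tests treat all values as independent. For H3K27ac each genotype had 1 female and 2 male animals. All coordinates are in mm10.

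Setdb1 itself (chromosome 3, 95323525 to 95357202) overlapped 0 of the H3K9me3 regions in the authors' deposited table. An H3K27ac peak lay in the gene or within 1 kb of it in all 3 KO libraries and in 2 of the 3 WT libraries. The strongest of these in KO replicate 1 spanned 95356227 to 95357173 and that in WT replicate 1 spanned 95356839 to 95357217, both at the same end of the gene. Histone peaks at this end do not show whether part of the gene was deleted, so they check neither the genotype labels nor the loss of the enzyme.

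Most listed H3K9me3 regions were lower in the KO progenitors. At an adjusted p of 0.05 or less, the authors' deposited table held 36027 regions with lower H3K9me3, covering 64.7 Mb, and 14615 with higher H3K9me3, covering 22.2 Mb. The median log2 fold change was -1.17 at the lower regions and 0.81 at the higher ones. These are counts of regions and not of reads. The region with the highest WT mean (chromosome 2, 98661301 to 98668300) took 39.7% to 56.9% of the reads in listed regions and was listed at -0.15. The 3 KO and the 3 WT values did not overlap at 76.3% of lower and 69.97% of higher regions. The 10% that chance gives 3 against 3 is no yardstick here, since the regions were selected for a difference between these same values. Values in reads given below are normalised, apart from the recovered reads. The authors' p-values follow a test on summed normalised values that leaves out the spread between animals. With that spread, limma on log2 values with Benjamini-Hochberg adjustment passed 7551 lower and 627 higher regions, and limma-voom on recovered reads passed 29385 and 7133. Scaled to the median ratio over the listed regions, which moved log2 fold changes by a median of 0.81, the authors' kind of test called 18085 lower and 16093 higher regions. This scaling sets the typical listed region to no change, and most were listed as lower. A more even split therefore follows from the scaling and is no check of the balance. The limma count of lower regions fell to 0 when any listed value other than the third KO value was left out (12340 to 20756 at an unadjusted p of 0.05), and rose to 30932 without that value. Limma-voom without the second KO value, the deepest, gave 7540 lower and 8743 higher regions.

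Most listed regions at clustered protocadherins and zinc finger genes had lower H3K9me3 in KO. All 82 regions annotated to clustered protocadherins, cell-surface proteins that give neurons individual identities, were lower, over 36 genes (Fisher's exact test, two-sided, adjusted p = 7.39e-12 against all other regions), and 23 of the 58 genes in the reference had no listed region. The 36 include Pcdha7-g, a symbol that the reference lists under another name, with 24 of the regions. Under median-ratio scaling 39 of these regions were called lower and 0 higher. The region at Pcdhga10 (chromosome 18, 37735401 to 37759800, promoter), had 312 ± 188 normalised reads in KO and 1956 ± 471 in WT (SD, n = 3), a log2 fold change of -2.65 in the authors' deposited table. Its neighbours at Pcdhgb5 (37724901 to 37735200) and Pcdhgb4 (37714601 to 37724600) were listed at -2.67 and -2.47. Of 366 regions at zinc finger protein genes, 358 were lower and 8 higher (Fisher's exact adjusted p = 3.78e-41), with 162 genes lower only, 2 higher only, 3 with both and 249 of 416 with no listed region under the symbols of the table. With outdated symbols replaced by current ones, 490 zinc finger regions were lower and 34 higher (Fisher's exact adjusted p = 3.12e-37), and 232 genes had no listed region. Zfp316 (chromosome 5, 143253501 to 143256200, gene body) had 28.0 ± 10.7 reads in KO and 208 ± 67.1 in WT (SD, n = 3). Zfp781 (chromosome 10, 81755501 to 81761400) was listed at -2.74, and Zfp300 and Zfp182 on X at -3.14 and -2.86. These 4 zinc finger regions passed limma (adjusted p = 0.0471). Among regions that pass limma, all 30 protocadherin regions were lower, against 92.3% of other regions. The list did not pass there (Fisher's exact adjusted p = 0.554). With every region already lower it had no room to pass, so this does not show that the enrichment vanished.

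**Figure D1:**
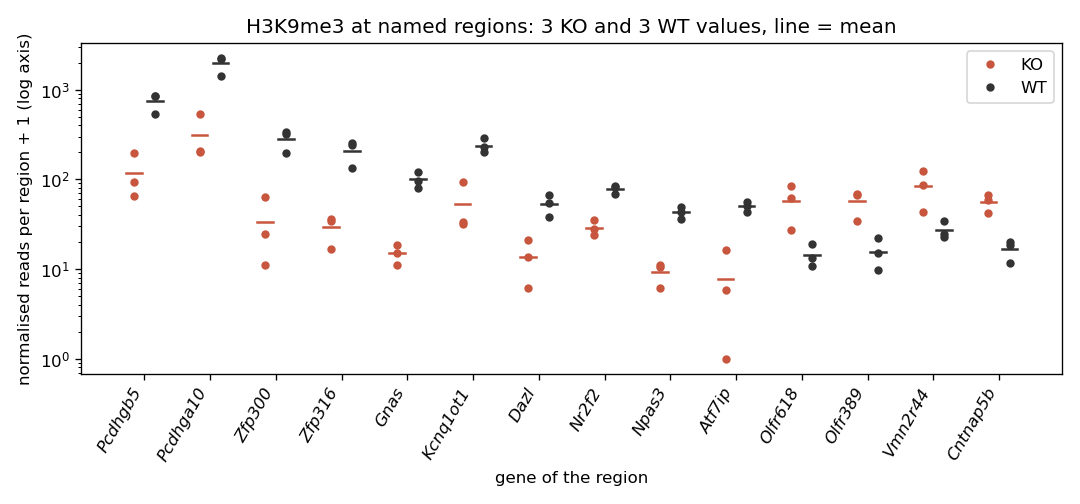
H3K9me3 in normalised reads per region plus 1 (log axis) at regions of named genes, with the 3 KO and 3 WT values as points and each mean as a line. At Pcdhga10 the KO mean was 312 and the WT mean 1956, while at Olfr618 the KO mean was 56.9 and the WT mean 13.5.

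Listed regions at chemosensory receptor genes were mostly higher in KO. Of 549 regions at olfactory and vomeronasal receptor genes, 503 were higher in KO and 46 lower (Fisher's exact test, two-sided, adjusted p = 6.43e-213), with 353 genes higher only, 16 lower only, 12 with both (2 of these symbols are not in the reference). Of the 2073 in the reference, 1694 had no listed region. Of the 549 regions, 31 passed limma, 25 of them higher and 6 lower. Under median-ratio scaling, which by itself moves listed regions upward, 506 were called higher and 7 lower. Olfr618 (chromosome 7, 103595801 to 103597000, promoter) had 56.9 ± 29.1 reads in KO and 13.5 ± 4.24 in WT (SD, n = 3; limma adjusted p = 0.0497, limma-voom adjusted p = 0.126). Olfr389 (chromosome 11, 73781901 to 73783300) was listed at 1.93 (limma-voom adjusted p = 0.0814) and Vmn2r44 (chromosome 7, 8377501 to 8379400) at 1.66 in the authors' deposited table. Olfr212 (chromosome 6, 116501701 to 116505500) was an exception, with a log2 fold change of -2.10. The authors' p is listed as 0 for 9887 regions. The 12 higher regions in genes with the largest fold changes among these also included Skint6, Klra15, Gm5615 and Cntnap5b, and 6 of the 12 were on Y. Of the 12, 7 passed limma and 6 limma-voom, and Skint6 passed neither (adjusted p = 0.053 and 0.14). Cntnap5b (chromosome 1, 99917501 to 99918800, gene body) had 55.2 ± 13.1 reads in KO and 15.8 ± 4.44 in WT (limma adjusted p = 0.0471). Many receptor genes are close copies of one another, and how shared reads were placed is not given in the sources used here, so values of single receptor genes are uncertain.

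Among regions with a listed p of 0, the 12 lower regions in genes with the largest fold changes lay at Gm35612, Psat1, Zfp300, Rhox13, Tspan5, Pvrl3, Map2k6, Scmh1, Dmd, Gpr50, Plcl1 and AU022751, with log2 fold changes from -3.53 to -2.95 in the authors' deposited table. Of these, 6 lay on X, all 12 passed limma-voom, and 5 passed limma, 4 of them on X. Gpr50 on X (71662201 to 71664700) had 15.1 ± 4.25 reads in KO and 119 ± 8.56 in WT (SD, n = 3; limma adjusted p = 0.0471). Psat1, an enzyme of serine synthesis (chromosome 19, 15926601 to 15927600), had 4.56 ± 4.01 and 40.7 ± 1.93 reads, and did not pass limma (adjusted p = 0.130; limma-voom adjusted p = 0.0271).

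Among imprinted genes, which are expressed from the copy of a single parent, 15 had lower regions only, 2 had higher regions only and 15 of the 32 had no listed region. Gnas (chromosome 2, 174297901 to 174300100) had 13.9 ± 3.73 reads in KO and 98.8 ± 20.5 in WT (SD, n = 3; limma adjusted p = 0.0471), and Kcnq1ot1 (chromosome 7, 143225901 to 143230200) had 52.0 ± 35.7 and 237 ± 42.9. Airn had 13.3 ± 3.24 and 53.4 ± 12.5 reads, and Grb10 was listed at -1.99 in the authors' deposited table. Snrpn (chromosome 7, 60080601 to 60081900), chosen after its values were seen, was higher, with 51.4 ± 7.04 reads in KO and 18.4 ± 4.02 in WT (limma adjusted p = 0.0475). With 31 regions lower and 8 higher, the list did not differ from other regions (Fisher's exact adjusted p = 0.341). All 16 regions at germline genes were lower (Fisher's exact adjusted p = 0.0267), among them Dazl, an RNA-binding protein of germ cells (chromosome 17, 50292901 to 50293900, log2 fold change -2.05), Dmrt1 (-2.36), Mov10l1 (-1.70) and Tdrd1 (-1.62). Of these 16 regions, 5 passed limma and 15 limma-voom. Among regions that pass limma-voom the list did not pass (Fisher's exact adjusted p = 0.152), nor did it in further settings given below. All 15 of its regions there were lower, against 80.5% of other regions, so a list of this size could not pass.

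Markers of interneurons from the caudal ganglionic eminence, the source of HTR3A interneurons, had 21 lower regions and 1 higher (Fisher's exact adjusted p = 0.0267). Nr2f2, a transcription factor of this lineage (chromosome 7, 70368601 to 70370300, promoter), had 27.9 ± 5.62 reads in KO and 77.0 ± 8.51 in WT (SD, n = 3; limma adjusted p = 0.0471). Npas3, Reln and Adarb2 were listed at -2.34, -1.90 and -1.82 in the authors' deposited table, and Htr3a was among the 13 members with no listed region. Of the 22 regions of this list, 4 passed limma and 18 limma-voom. Those named at Npas3 and Adarb2 did not pass limma (adjusted p = 0.0560 and 0.0702). Against gene-annotated regions alone the adjusted p rose to 0.183 for this list and to 0.111 for the germline list (Fisher's exact tests), and with each gene counted once to 1 for both. Counted once, all 4 caudal and all 7 germline genes were lower, against 81.2% of other genes, too few for either list to pass. Among regions that pass limma-voom the adjusted p was 0.119 for the caudal list (Fisher's exact test), with all 18 of its regions lower. Markers of the medial ganglionic eminence had 13 lower regions and 0 higher (Fisher's exact adjusted p = 0.0612) over 6 genes, among them Cux2 (-2.02), Sox6 (-1.74), Nkx2-1 (-1.65) and Lhx6 (-0.75), the last of which was at 0.02 under median-ratio scaling. Of the 13 regions of this list, 3 passed limma and 9 limma-voom. Those named at Nkx2-1 and Lhx6 passed neither (limma adjusted p = 0.0549 and 0.0899, limma-voom adjusted p = 0.0805 and 0.0527). On the autosomes alone this list passed (Fisher's exact adjusted p = 0.0346). Under median-ratio scaling 6 of its regions and 10 of the 16 at germline genes were called lower and 0 higher (Fisher's exact adjusted p = 0.0534 and 0.00587). The caudal list had 16 lower and 1 higher there (Fisher's exact adjusted p = 0.00123).

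The remaining lists did not pass the main test. Serotonin genes had 11 lower and 0 higher regions (Fisher's exact adjusted p = 0.0819) over 5 genes, among them Htr7 (-1.94), Htr1d (-1.38), Htr1f (-1.37) and Htr6 (-1.35), and 6 were called lower under median-ratio scaling. Of the 11, 0 passed limma and 10 limma-voom. Cortical excitatory markers had 10 lower and 1 higher (adjusted p = 0.260, Fisher's exact test), including Bcl11b (-2.13), Fezf2 (-1.62) and Tbr1 (-1.56). The genes of H3K9 methylation and repeat silencing had 10 lower and 1 higher region, 9 of them at Atf7ip, a partner protein of SETDB1 with a log2 fold change of -2.88 (list adjusted p = 0.260, and 0.0286 under median-ratio scaling, Fisher's exact tests). Of the regions of this list, 2 passed limma and 10 limma-voom, and the named Atf7ip region did not pass limma (adjusted p = 0.080). Pan-GABAergic genes had 7 lower regions (Ebf1, Slc32a1, Dlx5 and Isl1 among them), vascular markers 6 (Tek, Pdgfrb, Cdh5), neural progenitor genes 4 (Pax6, Hopx, Prom1) and interferon genes 2 (Zbp1, Mb21d1), each with 0 higher. Their adjusted p ran from 0.260 to 1 (Fisher's exact tests). Glial markers, microglia and blood markers, and p53 targets had 0 listed regions.

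By chromosome, X held 2031 lower and 8 higher regions, a lower share of 99.6% against 70.6% on the autosomes (Fisher's exact p = 3.04e-283). Y held 48 lower and 187 higher (Fisher's exact p = 1.82e-56). These 2 tests count regions of the same animals as independent and leave out the spread between animals, so their p-values are too small. At the higher regions on Y the medians of the 3 WT values were 0, 0 and 37.7 reads, and those of the KO values were 53.5, 45.8 and 54.6. At the lower regions on Y the WT medians were 62.9, 58.2 and 63.8 and the KO medians 28.0, 35.5 and 44.1. Since 2 of the 3 WT animals were female, these 48 regions cannot be taken as a change on Y itself. On the autosomes, chromosomes 10 and 18 were lower at 96.9% and 96.3% of regions. Chromosome 7 had 1771 lower and 3712 higher regions. Higher regions were concentrated, with 50% of them in 28 of the 556 windows of 5 Mb that held a region, against 173 windows for lower regions. The window with the most, on chromosome 14 from 40 to 45 Mb, held 546 higher and 45 lower regions. Regions in gene bodies were lower at 82.9%, and those in the table's 1 kb promoter class at 41.0%.

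**Figure D2:**
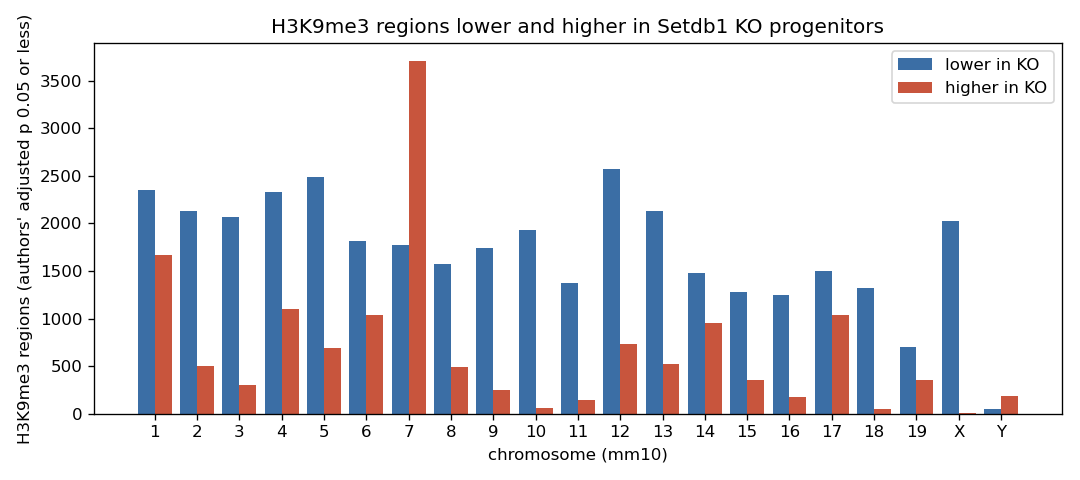
Number of H3K9me3 regions lower and higher in KO on each mm10 chromosome, at the authors' adjusted p of 0.05 or less. Chromosome 7 had 3712 higher and 1771 lower regions, and X had 2031 lower and 8 higher.

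No difference in the number of H3K27ac peaks was detected between genotypes. On chromosomes 1 to 19, X and Y, the KO libraries had 26344, 42651 and 11446 peaks and the WT libraries 31912, 37289 and 12446, a mean of 26810 ± 15610 against 27220 ± 13070 (SD, n = 3; exact permutation p = 0.9, two-sided, smallest possible 0.1). The lists of replicate 3 were the shortest in both genotypes. The share of peaks within 1 kb of a gene end was 42.8 ± 7.05% in KO and 42.2 ± 3.22% in WT (SD, n = 3; exact permutation p = 0.9). Each library shared the most regions, as a share of their union, with 1 library of the other genotype, which has the same replicate number here (numbers given in accession order), at 0.437, 0.572 and 0.437 for replicates 1, 2 and 3.

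**Figure D3:**
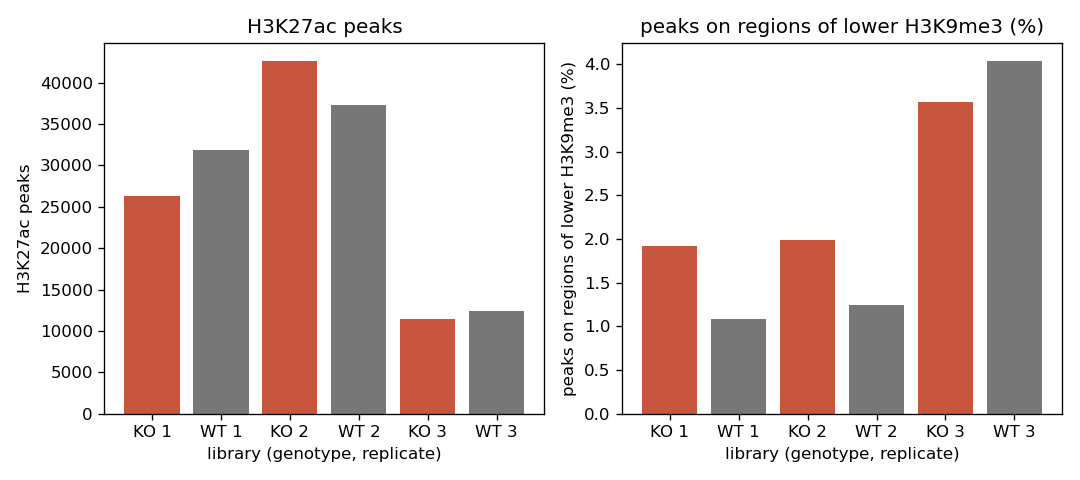
H3K27ac peaks per library (left, number) and their share on regions of lower H3K9me3 (right, percent), for KO and WT replicates. Replicate 3 had the fewest peaks, 11446 in KO and 12446 in WT, and the highest shares, 3.57% and 4.04%.

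Few merged H3K27ac regions had a peak in every library of 1 genotype and in none of the other. Of 62979 merged regions, 78 had a peak in all 3 KO libraries and no WT library, and 29 in all 3 WT and no KO library. Ranked by fold enrichment within each list, the authors' own value per peak, the leading KO-only genes were Pcdhgb4, Rps4l, Gm38450, Asmt, Stox2, Fam151b, Mras, Blvra, Gm28321, Gm51636, Gm39215 and Pcdhga2. The leading WT-only genes were Galnt10, Ints6, Mdga2, Sparc, Kcnh8, Ranbp3l, Gm31931, C030047K22Rik, Gm35071, Gm30388, Pakap and Ncoa1. Without KO replicate 3 the KO-only count was 885, and without WT replicate 3 the WT-only count was 796.

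Some KO-only H3K27ac regions lay where H3K9me3 was lower. Of the 78 KO-only regions, 21 overlapped a region of lower H3K9me3, against 0 of the 29 WT-only regions (Fisher's exact p = 0.000735) and 2.92% of regions with a peak in all 6 libraries. The Fisher tests of this contrast count merged regions as independent and leave out the spread between libraries, so their p-values are too small. None of either class overlapped higher H3K9me3, but only 148 of all 62979 merged regions did, so this says little about direction. In the protocadherin gamma cluster 4 KO-only regions did so, among them one at Pcdhgb4 (chromosome 18, 37720402 to 37720931) inside a region of H3K9me3 at -2.47 and one at Pcdhga2 (37668918 to 37669359) at -2.18. Others lay at Pcdhga10 (37746970 to 37747465), Zfp872 (chromosome 9, 22199663 to 22201242, H3K9me3 -1.88), 3300002I08Rik (chromosome 2, 150356921 to 150357513, -1.95) and Asmt, the last enzyme of melatonin synthesis (X, 170674921 to 170676479, -1.83). At equal list length the counts were 8 of 71 and 0 of 67 (Fisher's exact p = 0.00647), and at -log10 q of 5 or more 6 of 25 and 0 of 7 (Fisher's exact p = 0.296). Of regions with a peak in WT replicate 2 and both libraries of replicate 3 alone, 13 of 29 overlapped lower H3K9me3. Without KO replicate 3 the counts were 71 of 885 and 2 of 35 (Fisher's exact p = 1), and without WT replicate 1 they were 22 of 124 and 20 of 151 (Fisher's exact p = 0.317). Over all peaks of a library, 2.49 ± 0.93% in KO and 2.12 ± 1.66% in WT lay on lower H3K9me3 (SD, n = 3; exact permutation p = 0.6), and the difference was higher in KO in replicates 1 and 2 and lower in replicate 3.

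At the gene lists, no difference in H3K27ac near gene ends passed the test. The adjusted p was 1 for each of the 17 lists (exact permutation tests, Benjamini-Hochberg), in a design where no unadjusted p can go below 0.1. Zinc finger genes went both ways, with a peak at Zfp872 in 3 KO and 0 WT libraries, at Zfp13 in 3 and 1, and at Zfp660 and Zfp667 in 1 and 3 each. So did neural progenitor genes, with a peak at Nes in 0 KO and 2 WT libraries and at Sox1 in 2 KO and 0 WT libraries, and the mean number of such genes was 9 in KO and 8 in WT. Glial markers averaged 3.67 ± 1.53 genes in KO and 2 ± 2 in WT (SD, n = 3; exact permutation p = 0.5). Clustered protocadherins had a peak at 23, 23 and 4 genes in the KO replicates and at 23, 23 and 21 in the WT replicates. Many of these genes share 1 annotated end, so a single peak there counts for all of them. With lists of equal length the direction turned, to 8, 21 and 4 genes in KO and 1, 3 and 2 in WT (exact permutation p = 0.1, the smallest possible; adjusted p = 1), and at 2.5 kb the counts were 23, 23 and 21 against 23, 23 and 22. Zinc finger genes had one at 251 ± 76.7 of 416 genes in KO and 262 ± 59.0 in WT (SD, n = 3).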

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

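The replicate-aware tests, the scaling, the extra gene-list backgrounds, the current symbols, the start sites with a strand and the comparison of replicates 1 and 2 were chosen after seeing the data. Of 265 alternative values, 194 kept their direction and their side of the threshold, or a count within 1.5 times. The cause of the other changes was not tested, except where fewer libraries or regions entered.

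H3K9me3 counts were 23408 lower and 3648 higher at an absolute log2 fold change of 1 or more, 7551 and 627 by limma, 16857 and 2254 by limma with pseudocount 5, 29385 and 7133 by limma-voom, and 18085 and 16093 under median-ratio scaling. The last split follows from setting the typical listed region to no change. With 1 listed value left out, limma gave 0 to 30932 lower and 0 to 2986 higher regions, the highest without the third KO value. Where limma gave 0 lower regions, 12340 to 20756 passed an unadjusted p of 0.05. Limma-voom gave 7540 to 29807 lower and 2052 to 8743 higher. Of 5 gene lists that passed, 3 did with each gene counted once, 3 against gene-annotated regions, 2 on regions that pass limma and 3 on those that pass limma-voom. The lists that dropped out had only lower regions or genes there, except the caudal list against gene-annotated regions. Drops of lists with only lower entries do not show that an enrichment vanished. On the autosomes 6 lists passed, with medial ganglionic eminence markers added, and 6 under median-ratio scaling, with the silencing machinery added. Zinc finger genes and chemosensory receptors passed in all 9 alternatives. With outdated symbols replaced the same 5 lists passed, with 58 and 0 regions at protocadherins and 490 and 34 at zinc finger genes. The silencing machinery list turned to 66.7% lower, below other genes, with each gene counted once.

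KO-only H3K27ac regions numbered 25 at -log10 q of 5 or more, 29 with 50% of the region covered, 912 in replicates 1 and 2 alone, and 83 to 885 with 1 library left out. WT-only regions numbered 7 at -log10 q of 5 or more, 67 at equal list length, 812 in replicates 1 and 2 alone, and 35 to 796 with 1 library left out. KO-only regions on lower H3K9me3 numbered 6 of 25 at -log10 q of 5 or more, against 0 of 7 (24% and 0%, with 26.9% and 0% in the main setting; Fisher's exact p = 0.296), and 21 to 71 with 1 library left out. In replicates 1 and 2 alone they were 75 of 912 against 5 of 812 (Fisher's exact p = 4.38e-16).

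Differences of KO minus WT means that were not past the threshold changed sign. Peaks per library went from -402 to 866 at -log10 q of 5 or more, and from -8321 to 7282 with 1 library left out (1946 without WT replicate 1, 4635 without WT replicate 2). The share on lower H3K9me3 went from 0.37 to -0.11 percentage points at -log10 q of 5 or more, and from -0.17 to 1.33 with 1 library left out (-0.15 without WT replicate 1, -0.07 without WT replicate 2). The share near gene ends went from 0.59 to -1.30 at equal list length, to -0.21 with start sites that have a strand, and from -3.11 to 3.92 with 1 library left out (-0.95 without WT replicate 2). Replicate numbers were not used to pair libraries. Between same-numbered libraries the share on lower H3K9me3 differed by 0.83, 0.74 and -0.48 percentage points (KO minus WT), and every library was nearest to its own number. The 2 libraries of replicate 1 also share a first title number that no other H3K27ac library has, while replicates 2 and 3 share another. Permuting within the first number of the title left p at 0.833 for peaks and 0.667 for the share on lower H3K9me3 (exact permutation tests).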

Other observations

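Among the tests below, those on X as a whole, on the third listed KO value, on the limma count and on explanations of KO-only regions at lower H3K9me3 were chosen after the result was seen, while the KO-only overlap and its setting at equal list length were planned. The genes with the most lower regions were Gm13152, an older symbol of Zfp982, with 57 lower and 12 higher, Tmem132d with 43 and 2, Anks1b and Grip1 with 30 and 0 each, and Mtus2 and Park2 with 26 and 0 each. Those with the most higher regions were Cntnap5a with 79 higher and 5 lower, Gm6367 with 53 and 12, Cntnap5c with 51 and 4, Nell1 with 42 and 6, and Ano2 with 38 and 0. These were chosen after their values were seen.

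On X, 99.61% of regions were lower in KO, and on Y 187 of 235 were higher, in the directions that the sex of the libraries predicts. Sex may therefore account for part of the X and Y changes. As the whole cause on X it would leave KO no lower than the lowest WT value, since 1 WT animal was male. Over the X regions called lower, the median log2 ratio of mean KO to the lowest WT value was -0.58 (95% bootstrap interval -0.75 to -0.45) under the authors' scaling and 0.22 (-0.03 to 0.38) under median-ratio scaling. The scaling thus decides the sign. The regions were also selected for lower KO in these same values, which by itself favours a negative ratio. The bootstrap intervals here and below leave out the spread between animals. Only the third listed WT value had reads in the median at higher Y regions (37.7). Its median at these X regions was 58 under the authors' scaling, against 28.02, 40.55 and 40.34 in KO. Whether genotype adds to sex on X therefore stays open.

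The third listed KO value lay between the other 2 KO values and WT at lower regions, 0.49 of the way to WT. WT cells in that culture could give this, but at higher regions the value lay beyond the other 2, at -0.41 of the way (95% bootstrap interval -0.49 to -0.33). The higher regions were selected for higher KO values, the third included, which by itself favours such a result. The comparison thus cannot exclude WT cells. A scaling error alone would move both kinds of region alike, and the log2 ratio to the other 2 was 1.10 at lower and 0.23 at higher regions. A mixture together with a scaling difference, a difference in deletion and variation between animals stay open and were not tested. The real split gave 8178 regions by limma and the highest other split 154 (1 of 10 splits gave as many), and 10 splits are too few for a share under 0.05. The regions had also been selected for a difference between KO and WT in these libraries, which favours the real split, so this comparison says nothing about chance.

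A candidate explanation for KO-only H3K27ac at lower H3K9me3 is acetylation of regions that lost the silencing mark. The marks were profiled in different animals, so they were not seen to change together in any culture. List length alone would end the contrast at equal lengths, where 8 of 71 KO-only and 0 of 67 WT-only regions overlapped (Fisher's exact p = 0.00647). The real split gave 21 such regions and the highest other split 14 (1 of 10 splits gave as many), again too few splits for a share under 0.05. As a share of regions the real split was not the highest, with 26.9% for KO-only against 44.8% (13 of 29) for WT replicate 2 with both libraries of replicate 3, and 2 of 2 for WT replicate 1 with those 2. The contrast was lost without KO replicate 3 or WT replicate 1, 4 of the 21 regions lie in 1 gene cluster, and the share over all peaks did not pass its test. The total counts of 78 KO-only and 29 WT-only regions were reached by 7 and 9 of the 10 splits, with 1960 in the highest other, the one that joins the 3 libraries with the longest peak lists.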
